A study of Mus musculus with 4 samples.

How the data were processed

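Sorted tdTomato-positive, DAPI-negative lung cells of E16.5 mouse embryos were profiled in 4 libraries, 2 of Cre controls and 2 of Myrf mutants. Per the labels' protocols, lungs of 3 to 5 embryos were pooled per genotype, about 50000 cells were sorted, about 16000 were loaded per genotype, and libraries were made with the 10x Chromium 3' V3 kit. The deposited values were whole-number counts of UMIs per gene and cell barcode, with no normalization. They were made with Cell Ranger 6.0.2, per the file headers and the submitters' processing notes, on the mouse build mm10, per the submitters' processing notes. The release of the gene annotation, the settings for calling cell barcodes and the use of strand were not given in the sources used here. Groups and replicate numbers came from the sample titles. The files list 32285 genes, without a row for tdTomato or Cre, and 32158 of their gene IDs matched GENCODE vM21, from which locations are given (mm10, 1-based).

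The files held 418, 3969, 488 and 4711 barcodes for control libraries 1 and 2 and mutant libraries 1 and 2, in that order. Barcodes with at least 1000 detected genes and at most 15% mitochondrial UMIs passed, and 32.5, 9.12, 15.6 and 5.92% failed. Haemoglobin made up 34.3, 0.331, 9.47 and 24.2% of the UMIs of the barcodes that failed. Doublets were scored with Scrublet in scanpy 1.11.5, whose automatic threshold marked 7 of 8733 barcodes and so did not work. The barcodes with the highest scores were removed instead, at 0.8% per 1000 barcodes, which took 1, 104, 1 and 157 and left 8470 cells.

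Counts were scaled per cell and log-transformed, and 3000 variable genes were taken, leaving out mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and 448 genes that correlated with the cell cycle (r over 0.25). Values were centred within each replicate number over both genotypes, reduced to 30 principal components (scikit-learn 1.9.0) and clustered with the Leiden method (15 neighbours, resolution 0.4, igraph 0.11.9), which gave 12 clusters. A cluster was called X-like after the fixed marker list with the most members detected in at least 10% of its cells and at least 2-fold above the mean of the other clusters, with at least 3 members needed. A rule added after seeing the data left a cluster unnamed, as mixed, where at least 66% of the fixed markers lay within 2-fold of their mean in the other cells of its main library. Cluster 1 met it at 78.9%, and the next highest, cluster 12, stood at 50.7%. Before that rule, cluster 1 carried the name mesothelial-like, and the shares under that name are given as an alternative. The leading genes were Des, Tnnt2, Actc1, Tagln and Ramp1 for cluster 2, Smim41, Slc38a5, Adh1 and Tcf21 for cluster 3, Lef1, Pdgfra and Tcf7 for cluster 4, and Col4a4, Upk3b, Frem2 and Aldh1a2 for cluster 5. They were Crh, Myh11, Ednrb and Acta2 for cluster 6, Ptn, Dpt and Lum for cluster 8, and Col6a5, Igfbp3 and Lrrn4 for cluster 10. Clusters 7, 9, 11 and 12 held 108 epithelial-like, 81 endothelial-like, 49 pericyte-like and 34 immune-like cells.

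Cells are not replicates, so UMI counts were summed per library, over all kept cells or over mesenchymal-like cells, and tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no covariate. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Of 27 pathway lists and 14 cell type lists, 39 could be tested. Shares were compared by a two-sided exact permutation test over libraries. The distance in composition between libraries was the sum of the absolute differences in share, divided by 2. The edgeR steps were tested on simulated data with 200 changed genes per comparison. For all sorted cells, 14, 82, 100 and 100% of genes changed 2-, 4-, 8- and 16-fold were recovered among 15775 genes tested, with 6 false calls. For mesenchymal-like cells, 18, 94, 100 and 100% were recovered among 13844 genes, with 5 false calls. The simulation used the trended dispersion for every gene and no difference in cell composition, and changed only genes above a set expected count. Recovery in the real data can therefore be lower. Des and Krt19, with log2 changes of 3.70 and -3.35 (over 8-fold), did not pass in all sorted cells (edgeR adjusted p = 0.0851 and 0.0928). Replicate libraries were checked for identity, and chi-square over its degrees of freedom was 117 in controls and 245 in mutants, so none was counted as a repeat.

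The text names Myrf and Wt1 always. For all sorted cells it then takes the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 20 CPM and both mutant libraries on the same side of both controls, and for mesenchymal-like cells the 5 and 5 by the same rule. It also takes up to 4 members of each fixed list with the smallest p, of which the text names some and summarises the rest by list. Left out beforehand were Xist, Tsix, chromosome Y, mitochondrial and haemoglobin genes and unnamed gene models. The Y-linked genes counted per cell, beside Xist, were Ddx3y, Eif2s3y, Kdm5d and Uty. The other gene that rose in all sorted cells is not reported here.

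The lists, tests, cell filters and rule for named genes were fixed before the data were examined, while the doublet rate, the clustering settings and the score that names clusters were set with the data at hand. Alternatives tried were DESeq2 1.42.0, RLE normalization, no low-count filter, a replicate block, leaving out each library, all deposited barcodes, a stricter cell filter (2000 genes and 7.5% mitochondrial UMIs), doublets kept, equal numbers of cells, other cell types left out, resolutions of 0.2 and 0.7, and clustering without identity and called genes. Alternatives chosen after seeing the data left out the mixed barcodes or cluster 2. Comparisons within mesothelial-like cells were left out because 2 and 6 such cells remained in the mutants. A further test of genes in clusters picked for their skew between genotypes was run and set aside as circular.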

Results

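Myrf encodes a membrane-bound transcription factor, and the study asked what it does in the mesothelium, the epithelial layer that covers the lung. Mouse embryos carried floxed Myrf, a tamoxifen-dependent Cre recombinase expressed from the Wt1 gene, and a tdTomato reporter that stays on in recombined cells and their descendants. Tamoxifen was given at E12.5 (embryonic day) and lungs were collected at E16.5. Living tdTomato-positive cells were sorted and profiled by droplet single-cell RNA sequencing of transcript 3' ends. There were 4 libraries, 2 of Myrf mutants and 2 of Cre-carrying controls, each from pooled lungs of 3 to 5 embryos of a genotype. Lungs were assigned to a genotype by lung and cell shape and later typed by PCR, per the labels. The labels do not say whether the libraries of a genotype came from separate pools. The p-values therefore set a difference only against the spread between these libraries.

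The libraries differed widely in size, although about 16000 cells were loaded for each genotype. After filtering, control library 1 held 281 cells and 8175944 unique molecular identifiers (UMIs), and control library 2 held 3503 cells and 57965000 UMIs. Mutant library 1 held 411 cells and 20884697 UMIs, and mutant library 2 held 4275 cells and 80666128 UMIs. The median UMI count per cell was 29175 and 14313 in control libraries 1 and 2, and 38643 and 15966 in mutant libraries 1 and 2. Most barcodes of control library 2, 2032 of 3503, carried a mixed profile that resembled the whole library and stayed unnamed. The mix of male and female embryos also differed, counted after seeing the data in cells outside the mixed barcodes with UMIs of Xist or of 4 Y-linked genes but not of both. Cells with Xist made up 24.2% (52 of 215) and 56.25% (693 of 1232) of these in control libraries 1 and 2, and 64.8% (217 of 335) and 82.9% (3220 of 3883) in mutant libraries 1 and 2. Repeat loads of 1 pool would not give such a difference within a genotype. The share was higher in both mutants than in both controls, and no gene test separated it from genotype. Levels below are CPM, UMI counts summed over the cells of a library and scaled to a common total, and changes are log2 ratios of mutant over control with their standard error (SE).

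Myrf, the targeted gene (ENSMUSG00000036098, protein-coding, mm10 chromosome 19, 10208272 to 10240748), was lower in both mutant libraries. It stood at 76.0 and 48.6 CPM in control libraries 1 and 2, and at 19.1 and 7.2 CPM in mutant libraries 1 and 2. The log2 change over all sorted cells was -2.22 ± 0.41 (SE, n = 2 per group), and it did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.134). This call depended on the fit. Myrf passed with DESeq2 (Benjamini-Hochberg adjusted p = 1.39e-05), by edgeR without a low-count filter (adjusted p = 1.26e-06) and with the replicate block described further below. It also passed by edgeR without mutant replicate 1 or 2. Here and below, such fits leave 1 library in a group and assume that it varies like the other group. Myrf did not pass under RLE normalization, with all deposited barcodes, with the stricter filter, with doublets kept or without control replicate 1. The sources used here do not say which exons were floxed, and a 3' tag outside them would still be counted. This level therefore checks neither the deletion nor the labels. Myrf stood at 137 and 101 CPM in mesothelial-like cluster 5 of control libraries 1 and 2, and at 2.13 and 4.42 CPM in fibroblast-like cluster 3. Few mutant cells lay in cluster 5, so the sum does not separate missing cells from lower Myrf within cells. Smooth muscle-like cluster 2, described below, held 350 of 398 Myrf UMIs in mutant library 1 and 446 of 581 in mutant library 2. Myrf stood there at 25.2 and 15.2 CPM. Wt1 (ENSMUSG00000016458, chromosome 2, 105126529 to 105173616), the site of the Cre driver and a mesothelial transcription factor, stood at 82.1 and 78.2 CPM in controls and 25.2 and 13.7 CPM in mutants. Its log2 change was -2.02 ± 0.28 (edgeR adjusted p = 0.0718). Wt1 too passed with DESeq2 (adjusted p = 2.58e-06 by Benjamini-Hochberg), with the replicate block and by edgeR without mutant replicate 1 or 2. Under the settings given above in which Myrf did not pass, Wt1 did not pass either. It stood at 146 and 150 CPM in cluster 5 of controls and at 1.42 and 4.16 CPM in cluster 3, so missing cells limit this sum as well. Reads of its antisense RNA Wt1os could be counted with it if strand was not used, which the sources do not state.

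The first comparison asked which genes differed between all sorted mutant and control cells, a population set by the sort and not by expression. Genes that mark mesothelium were far lower in the mutant libraries. Upk3b, a uroplakin of the mesothelial surface (ENSMUSG00000042985, chromosome 5, 136038496 to 136046487), stood at 965 and 659 CPM in controls and 8.77 and 7.01 CPM in mutants, and fell by 6.61 ± 0.39 on the log2 scale (edgeR quasi-likelihood, adjusted p = 0.00538). Lrrn4, a leucine-rich repeat membrane protein (ENSMUSG00000043110, chromosome 2, 132868305 to 132880891), fell by 6.18 ± 0.37, from 133 and 98.1 CPM to 1.20 and 1.65 CPM (edgeR adjusted p = 0.00538). Of 16242 genes tested, 47 fell and 2 rose.

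The 10 largest falls named by the rule also held the carbonic anhydrase gene Car9, which fell by 6.27, the uroplakin gene Upk1b, which fell by 5.86, and the claudin gene Cldn15, which fell by 5.72. The others were Bst1, which encodes a cell-surface ectoenzyme and fell by 5.72, Pnoc, which encodes a neuropeptide precursor and fell by 5.71, and Slc26a7, which encodes an anion transporter and fell by 4.86. Tmem151a fell by 4.75 and the X-linked kinase gene Stk26 fell by 4.23. Adjusted p-values of these 8 genes lay between 0.00445 and 0.0137 (edgeR quasi-likelihood, Benjamini-Hochberg). Within the libraries numbered 1, Upk3b was lower by a log2 ratio of -6.76, and within those numbered 2 by -6.44. No rise reached the mean of 20 CPM that the rule required. Of the genes that rose, Ccl7, a chemokine gene, was named after its values were seen. It rose by 2.73 ± 0.29 (edgeR adjusted p = 0.0385), from 5.26 and 3.62 CPM to 35.3 and 20.8 CPM. That call was lost without control replicate 1 (edgeR adjusted p = 0.0692), without control replicate 2 (0.0534), at equal cell numbers (0.0939) and with mixed barcodes left out, chosen after seeing the data (0.0768).

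**Figure D1:**
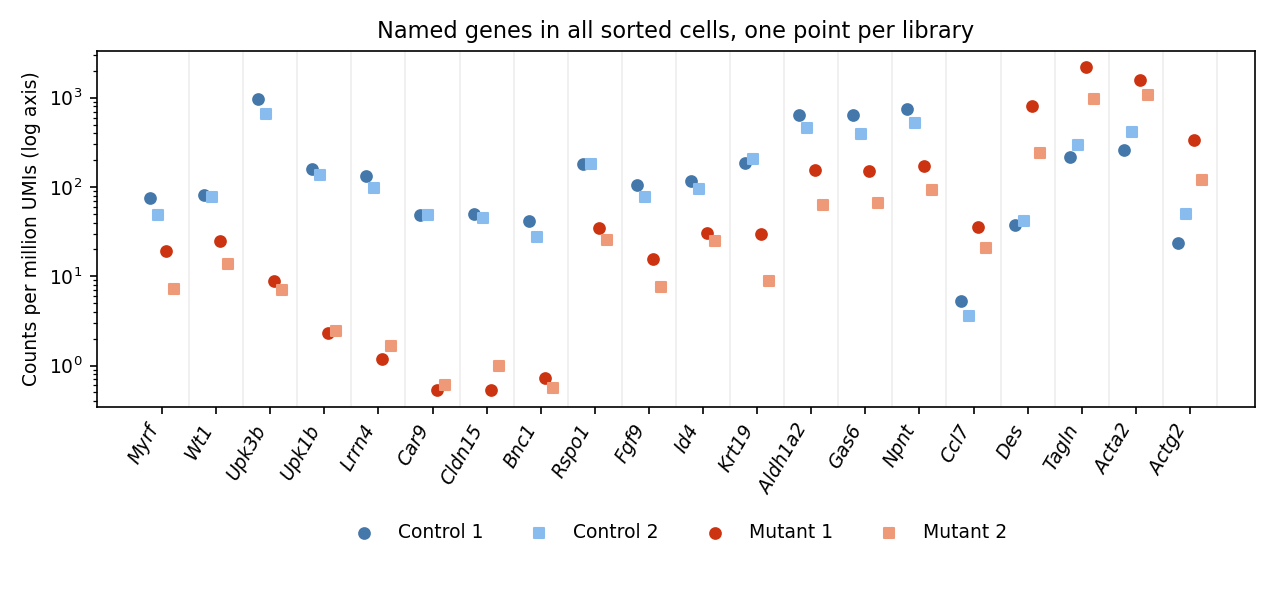
CPM (log axis) of 20 genes in all sorted cells, with a point for each of the 4 libraries, controls in blue and mutants in red. Upk3b lies at 965 and 659 CPM in controls and 8.77 and 7.01 CPM in mutants, and Des lies at 37.7 and 41.8 CPM in controls and 810 and 240 CPM in mutants.

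The list of mesothelial identity genes, fixed before the data were examined, was lower as a group. Of its 29 tested members, 10 fell and 0 rose over all genes, while 22 fell and 1 rose when adjusted over the list alone, and the median log2 change was -2.32. By camera, a test of a list against the other genes, its adjusted p was 1.67e-99, and its adjusted p was 0.278 with an estimated correlation between genes. Bnc1, a zinc finger gene of mesothelium, fell by 5.68 ± 0.31 (edgeR adjusted p = 0.00445). Of 51 secreted ligands, 2 fell and 0 rose, with 4 falls when adjusted over the list alone, and the list was called lower by camera (adjusted p = 0.00316, and adjusted p = 0.656 with an estimated correlation). Rspo1, an enhancer of Wnt signalling (ENSMUSG00000028871, chromosome 4, 124986430 to 125009099), fell by 2.53 ± 0.26, from 180 and 183 CPM to 34.8 and 25.8 CPM (edgeR adjusted p = 0.0308). Fgf9, a growth factor of the lung surface (ENSMUSG00000021974, chromosome 14, 58070547 to 58112720), fell by 2.94 ± 0.33, from 105 and 78.0 CPM to 15.7 and 7.64 CPM (edgeR adjusted p = 0.0420). Without control replicate 1 neither passed (edgeR adjusted p = 0.0586 for Rspo1 and 0.0515 for Fgf9). Gas6, a ligand of TAM receptor kinases, had a log2 change of -2.23 and did not pass (edgeR adjusted p = 0.137). It did pass with DESeq2 (adjusted p = 1.26e-06) and by edgeR without mutant replicate 1. In mesothelial-like cluster 5 of controls, Rspo1 stood at 339 and 359 CPM, Fgf9 at 204 and 180 CPM and Gas6 at 1231 and 947 CPM. In fibroblast-like cluster 3 of controls they stood at 11.4 and 16.9, 1.42 and 1.04, and 32.7 and 43.2 CPM. These changes therefore do not separate a loss of cluster 5 cells from lower levels within cells. In mutant libraries 1 and 2, cluster 2 held 653 of 726 and 1652 of 2079 Rspo1 UMIs. It held 266 of 328 and 559 of 616 Fgf9 UMIs, and 2692 of 3131 and 3390 of 5303 Gas6 UMIs. Levels there were 47.0 and 56.5 CPM for Rspo1, 19.1 and 19.1 CPM for Fgf9, and 194 and 116 CPM for Gas6.

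Basement membrane genes were called lower as a list by camera, with 0 of 26 members passing over all genes and 5 falls when adjusted over the list alone. The list's median was -0.51 (camera adjusted p = 6.34e-06, and adjusted p = 0.656 with an estimated correlation). Its members Frem2 and Npnt, both of the extracellular basement layer, had log2 changes of -3.03 and -2.21 (edgeR adjusted p = 0.0928 and 0.0968). Frem2, Npnt, Col4a3 and Col4a4 of this list were among the 10 leading genes of mesothelial-like cluster 5, nearly missing from mutants, so the test does not separate a loss of those cells from lower levels within cells. Both passed without mutant replicate 1 (edgeR adjusted p = 2.37e-09 and 0.000555) and without mutant replicate 2 (0.00492 and 0.0477), and Frem2 also without control replicate 2 (0.0327). The hedgehog list held pathway members beside targets. Of its 13 genes, 11 were lower, 0 passed over all genes and 1 fell when adjusted over the list alone. The median was -0.44 (camera adjusted p = 0.0106, and adjusted p = 0.656 with an estimated correlation). Its member Hhip stood at 1158 CPM in cluster 5 of control library 2, against 688 CPM in all cells there outside the mixed barcodes. For Hhip, too, a loss of those cells is not separated from lower levels within cells. The hedgehog co-receptor gene Gas1 had a log2 change of -1.22 and the transcriptional effector gene Gli1 of -0.96 (edgeR adjusted p = 0.167 and 0.337), and Gli1 passed without mutant replicate 1 (edgeR adjusted p = 0.0249). Id4, a BMP-responsive gene, fell by 1.86 ± 0.22 (edgeR adjusted p = 0.0498), while its list was not called (camera adjusted p = 0.0643). The call of Id4 was lost without control replicate 1 (edgeR adjusted p = 0.173), without control replicate 2 (0.0775), with all deposited barcodes (0.0509), with doublets kept (0.0521) and at equal cell numbers (0.0640). Krt19, a keratin of mesothelium, had a log2 change of -3.35 and Aldh1a2, an enzyme of retinoic acid synthesis, of -2.29, and neither passed (edgeR adjusted p = 0.0928 and 0.134). With other cell types left out, Krt19 fell by 4.67 and passed (edgeR adjusted p = 0.00459). Krt19 and Aldh1a2 passed without mutant replicate 1 (edgeR adjusted p = 2.24e-15 and 2.84e-05) and without mutant replicate 2 (0.000750 and 0.0477), and Krt19 also without control replicate 2 (0.0293).

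Genes of the contractile apparatus of smooth muscle were called higher as a list. Of 19 members, 18 were higher, 0 passed over all genes and 7 rose when adjusted over the list alone, with a median of 1.01 (camera adjusted p = 6.30e-14, and adjusted p = 0.656 with an estimated correlation). Des, the intermediate filament of muscle (ENSMUSG00000026208, chromosome 1, 75360329 to 75368579), stood at 37.7 and 41.8 CPM in controls and 810 and 240 CPM in mutants, a log2 change of 3.70 ± 0.56 (edgeR adjusted p = 0.0851). Tagln, Actg2 and Acta2, which encode an actin-binding protein and muscle actins, had log2 changes of 2.63, 2.58 and 1.98 (edgeR adjusted p = 0.137, 0.210 and 0.199). All 4 genes passed at equal cell numbers (edgeR adjusted p = 0.0218 to 0.0473), without mutant replicate 1 (5.22e-12 to 0.0113) and without mutant replicate 2 (1.03e-05 to 0.0318). Smooth muscle-like cluster 2, with 1 and 20 cells in controls, held 16123 of 16898 Des UMIs in mutant library 1 and 17700 of 19346 in mutant library 2. For Acta2 it held 28739 of 32671 and 51127 of 86257. These rises therefore do not separate a larger share of cluster 2 cells from higher levels within cells. Cell cycle genes were higher in 29 of 30 members with a median of 0.48, and 0 passed over all genes or over the list alone. That list was called by camera (adjusted p = 7.31e-05, and adjusted p = 0.692 with an estimated correlation). The replication gene Mcm3 had a log2 change of 0.73 and the checkpoint kinase gene Bub1b of 0.63 (edgeR adjusted p = 0.403 and 0.529). In the list of epithelial junction and polarity genes the signs differed, with a median of 0.14, a mean of -0.18 and a direction of lower by camera, which did not call it (adjusted p = 0.0645). With mixed barcodes left out, chosen after seeing the data, camera called it lower (adjusted p = 0.0258, and adjusted p = 0.743 with an estimated correlation).

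In all, camera called 19 of 39 lists, 8 higher and 11 lower, and none was called with an estimated correlation (lowest adjusted p = 0.20) or by fry (lowest adjusted p = 0.0895). Leaving out 1 library moved the count of 49 genes to 94 without control replicate 2, to 1159 without mutant replicate 1 and to 529 without mutant replicate 2. The count was 480 with DESeq2. With the mixed barcodes left out, chosen after seeing the data, 49 genes passed (edgeR quasi-likelihood), 45 of them among the 49 above.

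The second comparison asked which kinds of cells made up the sorted population. Mesothelial-like cells, in clusters 5 and 10, were nearly missing from the mutant libraries. They made up 40.2% (113 of 281) and 21.2% (743 of 3503) of cells in control libraries 1 and 2, and 0.487% (2 of 411) and 0.140% (6 of 4275) in mutant libraries 1 and 2. The mean was 30.7% ± 13.4 (SD, n = 2) in controls and 0.313% ± 0.245 (SD, n = 2) in mutants, a difference of -30.4 percentage points (two-sided exact permutation test, p = 0.333). That is the smallest p that 2 libraries against 2 can give, so this test cannot reach 0.05 here. The exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only, were 34.4 to 46.2% and 19.9 to 22.6% in controls, and 0.0590 to 1.75% and 0.0515 to 0.305% in mutants. Clustering without the mesothelial identity genes and the genes called above gave 113 and 747 mesothelial-like cells in controls and 3 and 6 in mutants. Those clusters were still named by the fixed mesothelial markers, which share genes with the identity list. This setting therefore cannot separate missing cells from cells with lowered markers.

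Cells with mesenchymal profiles, which are fibroblast-like, smooth muscle-like or pericyte-like, took the larger share in mutants. They made up 42.0% and 19.4% of cells in control libraries 1 and 2, and 92.7% and 97.1% in mutant libraries 1 and 2. The mean was 30.7% ± 15.97 (SD, n = 2) in controls and 94.9% ± 3.11 (SD, n = 2) in mutants, a difference of 64.2 percentage points (two-sided exact permutation test, p = 0.333). The exact 95% intervals were 36.2 to 48.0% and 18.1 to 20.8% in controls, and 89.7 to 95.0% and 96.6 to 97.6% in mutants. Clustering without the identity and called genes gave a difference of 49.7 points. The clusters that held the class differed between groups. Cluster 2, smooth muscle-like, held 1 and 20 cells in controls and 257 and 1419 in mutants, or 62.5% and 33.2% of mutant cells. Cluster 6, also smooth muscle-like, held 6.76% and 4.71% of control cells and 6.57% and 7.58% of mutant cells. Fibroblast-like clusters held 31.0% and 13.8% of control cells and 23.1% and 55.7% of mutant cells.

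The mixed barcodes enter these shares as unnamed cells. They made up 4.63% and 58.0% of control libraries 1 and 2 and 0.243% and 0.164% of mutant libraries 1 and 2. In control library 2, 56 of 71 fixed cell type markers (78.9%) lay within 2-fold of their mean in the other cells, and the limit of 66% that left such a cluster unnamed was set after seeing the data. With these barcodes left out, an alternative chosen after seeing the data, mesothelial-like cells made up 42.2% and 50.5% of controls and 0.488% and 0.141% of mutants, a difference of -46.0 points (two-sided exact permutation test, p = 0.333). Mesenchymal-like cells then made up 44.0% and 46.2% of controls and 92.9% and 97.3% of mutants. Cluster 2 then held 0.373% and 1.36% of control cells and 62.7% and 33.2% of mutant cells, and cluster 6 held 7.09% and 11.2% against 6.59% and 7.59%. Fibroblast-like clusters held 32.5% and 33.0% of control cells and 23.2% and 55.8% of mutant cells, so their share was lower in mutant library 1 and higher in mutant library 2. Counting the mixed barcodes as mesothelial-like gave a difference of -61.5 points.

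**Figure D2:**
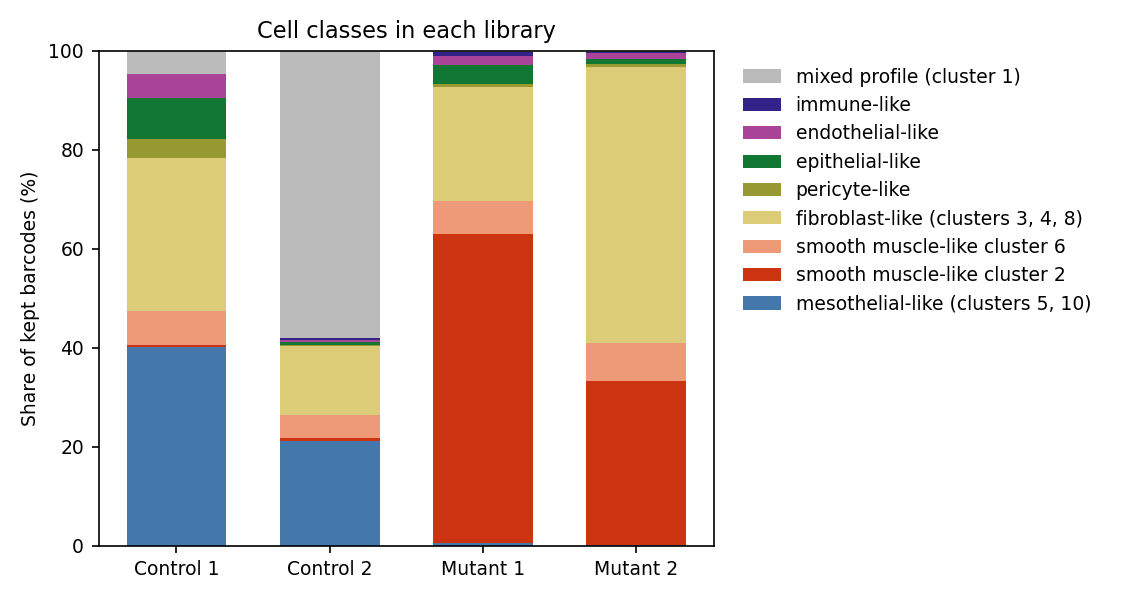
Share of kept barcodes (%) in each cell class, stacked, for the 4 libraries. Mesothelial-like cells take 40.2% and 21.2% of controls and 0.487% and 0.140% of mutants, smooth muscle-like cluster 2 takes 62.5% and 33.2% of mutants, and mixed barcodes take 58.0% of control library 2.

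**Figure D3:**
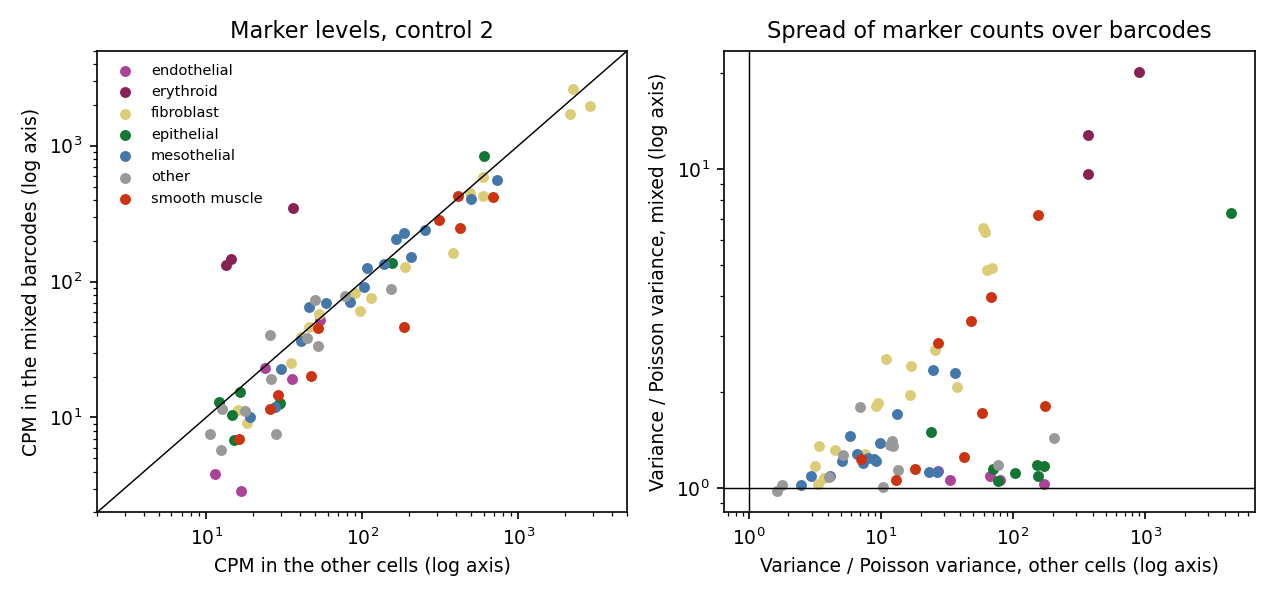
Fixed cell type markers in control library 2, with a point for each of 71 genes. The left panel plots CPM in the mixed barcodes against CPM in the other cells (log axes), where 56 genes lie within 2-fold of the diagonal, and the right panel plots the variance over barcodes divided by the Poisson variance (log axes), with a median of 1.28 in mixed barcodes and 18.1 in the other cells.

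Cluster 2 was set apart by muscle genes, which define it and are given as a description, not as a result. In mutant libraries 1 and 2 it held Des at 1160 and 605 CPM, Tagln at 3116 and 2127 CPM and the troponin gene Tnnt2 at 632 and 570 CPM. Its level of Myh11, the smooth muscle myosin heavy chain, was 501 and 190 CPM, against 1487 and 601 CPM in cluster 6 of the same libraries. Tnnt2 was not particular to muscle-like cells. It stood at 158 and 156 CPM in mesothelial-like cluster 5 of controls, and at 39.8 and 5.69 CPM in cluster 6 of the mutants. Cluster 2 also held mesothelial transcripts, most of them at lower levels than mesothelial-like cells. Wt1 stood at 35.5 and 31.8 CPM there, against 146 and 150 CPM in mesothelial-like cluster 5 of controls and 0 and 0.190 CPM in cluster 6 of the mutants. The mesothelin gene Msln stood at 77.5 and 42.8 CPM in cluster 2, against 146 and 128 CPM in cluster 5 of controls. Upk3b stood at 5.83 and 13.5 CPM in cluster 2, against 1876 and 1589 CPM in cluster 5 of controls. Krt18, a keratin gene of the mesothelial identity list, was not lower, at 62.4 and 64.5 CPM in cluster 2 and 44.6 and 64.0 CPM in cluster 5 of controls. These cluster values were chosen after they were seen and carry no test.

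**Figure D4:**
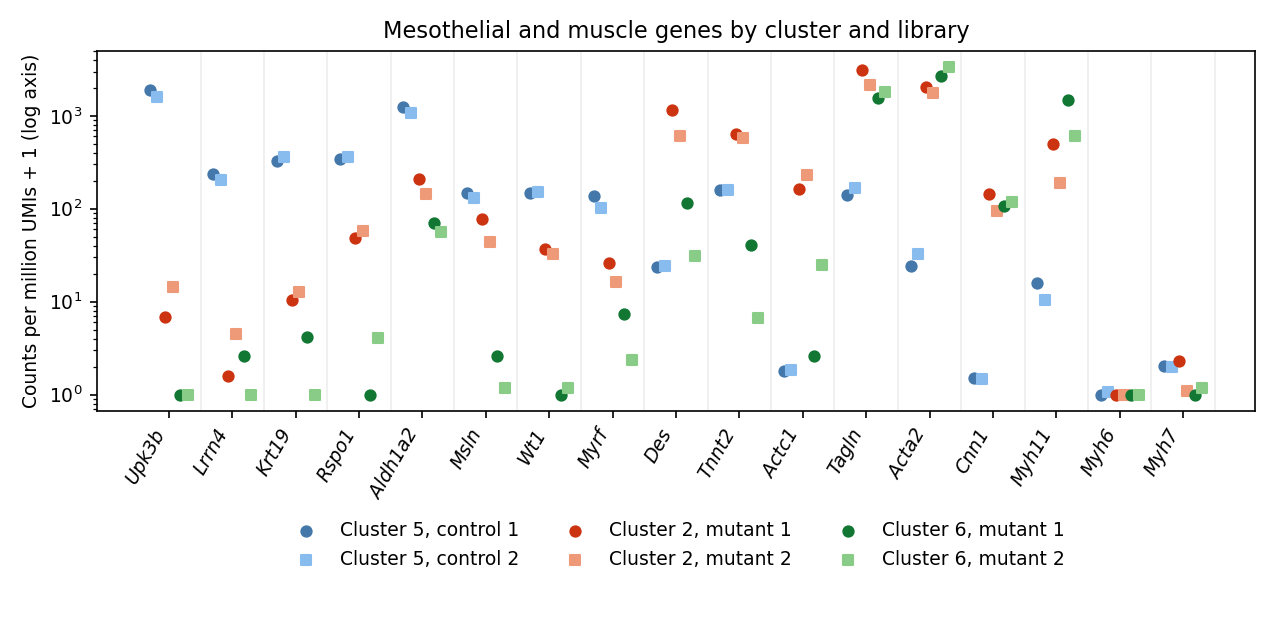
CPM plus 1 (log axis) of 17 mesothelial and muscle genes in cluster 5 of the control libraries and clusters 2 and 6 of the mutant libraries, with a point per library. Upk3b lies at 1876 and 1589 CPM before the addition in cluster 5 and at 5.83 and 13.5 CPM in cluster 2, while Wt1 in cluster 2 lies at 35.5 and 31.8 CPM.

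The third comparison asked which genes differed within mesenchymal-like cells, a class that can hold descendants of mesothelium through the Wt1 lineage label. Of 14331 genes tested, 2 rose and 0 fell (edgeR quasi-likelihood), with 1207 genes at an unadjusted p under 0.05 and 361 called by DESeq2. Myl7, an atrial myosin light chain (ENSMUSG00000020469, chromosome 11, 5896637 to 5898782), rose by 4.87 ± 0.39 (edgeR adjusted p = 0.0495), from 0.911 and 1.72 CPM to 37.9 and 44.4 CPM. Myl7 was also present in mesothelial-like cluster 5 of controls, at 98.3 and 113 CPM. The chemokine gene Cxcl10 was named after its values were seen, since its mean was 7.87 CPM, and it passed the test (edgeR adjusted p = 0.0495). Cxcl10 stood at 0 and 0.127 CPM in controls, with 2 UMIs in all, and at 17.4 and 14 CPM in mutants. Cluster 2 held 287 of its 314 UMIs in mutant library 1 and 1057 of its 1084 UMIs in mutant library 2. In mutant library 1, Cxcl10 stood at 20.6 CPM in cluster 2 and at 34.4 CPM (27 UMIs over 31 cells) in fibroblast-like cluster 3. In mutant library 2 these levels were 36.1 and 0.262 CPM. Outside the class, Cxcl10 stood at 0 and 6.95 CPM in mesothelial-like cluster 5 of control libraries 1 and 2.

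Different clusters held the class in each group, with cluster 2 giving 257 of 381 mesenchymal-like cells in mutant library 1 and 1419 of 4151 in mutant library 2. With cluster 2 left out, an alternative chosen after seeing the data, 0 of 13102 genes tested passed (edgeR quasi-likelihood). Of these, 249 had an unadjusted p under 0.05, a smaller share than that threshold gives by itself with no change. The fit was therefore conservative, and 0 calls do not show that the other mesenchymal-like cells were unchanged. The log2 change of Myl7 was -0.085. Neither gene passed under RLE normalization (edgeR adjusted p = 0.0524 for both), with all deposited barcodes (0.0895 for Myl7 and 0.0922 for Cxcl10), with the stricter filter (0.143 and 0.0693), with doublets kept (0.0938 for both) or without control replicate 2 (0.0662 for both). With the clustering resolution raised Myl7 did not pass (edgeR adjusted p = 0.0689) while Cxcl10 did (0.0375), and at equal cell numbers Myl7 did not pass (0.0580). The count was 5 without control replicate 1, 0 without control replicate 2, 365 without mutant replicate 1 and 800 without mutant replicate 2. A comparison within mesothelial-like cells, of their gene lists, and of the difference between the classes was not made, because the mutant libraries held 2 and 6 such cells, under the 20 per library set beforehand.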

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

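The count of genes changed in all sorted cells (49) lay between 44 and 62 under RLE normalization, all deposited barcodes, the stricter filter, doublets kept, equal cell numbers and, chosen after seeing the data, mixed barcodes left out. It was 733 without a low-count filter, 480 with DESeq2, 121 with other cell types left out and, chosen after seeing the data, 112 with mixed barcodes also left out. Leave-one-out counts ran from 34 to 1159 (34 without control replicate 1, 94 without control replicate 2, 1159 without mutant replicate 1, 529 without mutant replicate 2), with the lone library assumed to vary like the other group, and shared 31, 44, 49 and 49 genes with the 49. In mesenchymal-like cells the count of 2 became 0 under RLE normalization, all deposited barcodes, the stricter filter, doublets kept and equal cell numbers, 823 without a low-count filter and 361 with DESeq2. By settings chosen after seeing the data it became 0 with cluster 2 left out and 21 with clustering without identity and called genes. Leave-one-out counts there ran from 0 to 800. With cluster 2 left out the log2 change of Myl7 turned to -0.085, since the cells that held it were removed, and Cxcl10 gave no value there or at equal cell numbers. Apart from that removal, the cause was not tested. With the replicate block, the counts were 478 in all sorted cells, 31 in mesenchymal-like cells and 22 lists, with the epithelial junction (camera adjusted p = 0.0119), BMP response (0.0324) and Hippo target lists (0.0486) added. With an estimated correlation their adjusted p was 0.807, 0.721 and 0.721, and fry called the pericyte list lower (adjusted p = 0.0231). Of 15 named genes not called, 12 passed with that block, among them Myrf (edgeR adjusted p = 0.00829) and Wt1 (0.0111). Libraries of the same number deviated together with a correlation of 0.358 in all sorted cells and 0.179 in mesenchymal-like cells, over 2 pairs that no label ties to a litter or day.

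The 19 lists called by camera became 0 with an estimated correlation and 0 with fry, and leave-one-out gave 13 to 20. The mesothelial-like difference of -30.4 points was -46.0 with mixed barcodes left out and -61.5 with them counted as mesothelial-like, both chosen after seeing the data, and -39.9 to -20.9 by leave-one-out. The mesenchymal-like difference of 64.2 points ran from 52.9 to 75.5 by leave-one-out. No other setting moved either share by more than the spread between libraries. For named genes called in all sorted cells, 213 values under alternatives kept their side of the threshold and 12 lost it, 4 of them without control replicate 1, and for those not called 159 kept it and 66 passed. The alternatives listed beforehand within mesothelial-like cells and for the difference between classes were not run, since 2 and 6 such cells remained in the mutants. Control library 1 held the fewest cells (281) and UMIs (8175944), although its median UMI count per cell (29175) was above those of both libraries numbered 2.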

Other observations

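The tests of explanations for the mixed barcodes, cluster 2 and the missing mesothelial-like cells in this part were chosen after those results were seen, while the list tests were not. Among the fixed lists of other cell types, camera called immune markers higher in mutants (median log2 change 1.38, adjusted p = 0.000902), and likewise erythroid (0.96, adjusted p = 0.0302) and cardiomyocyte markers (0.97, adjusted p = 0.00317). It called lymphatic endothelial (-1.15, adjusted p = 0.0116) and endothelial markers (-0.57, adjusted p = 0.0499) lower. Endothelial-like and immune-like cells did not follow genotype in both pairs of libraries, and cells of the other 3 kinds formed no cluster. Endothelial-like cells made up 4.98% and 0.371% of control libraries 1 and 2 and 1.95% and 1.08% of mutant libraries 1 and 2. Immune-like cells made up 0% (0 of 281) and 0.485% (17 of 3503) of controls and 0.730% (3 of 411) and 0.327% (14 of 4275) of mutants. With an estimated correlation the adjusted p was 0.656 for the first 4 lists and 0.696 for endothelial markers. With the mixed barcodes left out, chosen after seeing the data, the erythroid median was 2.54 (camera adjusted p = 1.57e-16, and adjusted p = 0.352 with an estimated correlation), 2 of its members rose over all genes and 4 rose when adjusted over the list alone. With all barcodes kept, no member of these 5 lists passed over all genes by edgeR, and 2 cardiomyocyte markers rose and 2 lymphatic markers fell when adjusted over the list alone. Camera also called the TGF-beta response list (median 0.39, adjusted p = 0.000364) and the p53 list (median 0.49, adjusted p = 0.0124) higher, and the lung fibroblast (-0.16, adjusted p = 0.0263), dissociation stress (-0.32, adjusted p = 0.0191) and keratin lists (-0.14, adjusted p = 0.0195) lower. With an estimated correlation their adjusted p was 0.656, 0.656, 0.656, 0.697 and 0.696. The keratin list was not called with the mixed barcodes left out (camera adjusted p = 0.0529).

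In cluster 6, the smooth muscle-like cluster found in both groups, the muscle actin gene Actc1 stood at 188 and 254 CPM in controls and 1.59 and 23.7 CPM in mutants, over 19, 165, 27 and 324 cells. In cluster 2 of the mutants Actc1 stood at 161 and 230 CPM. Actc1 is a leading gene of cluster 2, so its level in cluster 6 also depends on which cells were assigned to cluster 2. No test of these values was made.

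Most barcodes of control library 2 carried markers of many cell types together, and in these barcodes the surfactant gene Sftpc stood at 845 CPM, against 608 CPM in the other cells and 30.03 CPM in mesothelial-like cluster 5 of that library. Doublets of mesothelial-like and other cells would carry more UMIs than single cells, and the median was 0.494 times that of cluster 5, which argues against them. Free RNA of the whole library as exactly one mixture in every barcode is argued against by a median of 2.35 times the Poisson variance. That median covers the 27 fixed markers with a mean of at least 1 UMI per barcode, 16 of which exceeded 2 times. It lay only slightly above the limit of 2. Sftpc, Acta2 and Upk3b, for example, stood at 7.27, 7.20 and 2.30 times the Poisson variance, against 4419, 155 and 36.2 times in the other cells. A mixture shared in large part is therefore not excluded. Over all 71 markers the median was 1.28 times the Poisson variance, against 18.1 in the other cells. Marker counts thus varied far less over these barcodes than over the other cells. That median does not tell exactly one mixture from a mixture that varies in part, since a small variation barely shows in markers with few UMIs. Hbb-bs, Hba-a1 and Hbb-bt stood at 9.69, 10.1 and 9.90 times their level in the other cells. Free RNA of varying make-up, in droplets or in damaged cells, is a candidate explanation that stays open, and no biological explanation was tested.

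Cluster 2, nearly all from mutants, joined muscle genes with mesothelial ones. Smooth muscle cells of the kind in cluster 6 are argued against by a median log2 ratio of identity genes, cluster 2 over cluster 6, of 2.74 and 2.90 in mutant libraries 1 and 2. Cardiomyocytes are argued against by the 8 other markers of their list, at a median of 0.376% and 0.561% of the level of Tnnt2, although Myl7 stood at 48.6 and 116 CPM, Ryr2 at 26.04 and 13.8 CPM, Nppa at 7.41 and 5.81 CPM and Myl4 at 3.45 and 36.1 CPM. Doublets of mesothelial-like and smooth muscle-like cells are argued against by low mesothelial markers. Their median was 9.34% and 8.49% of the level in cluster 5 of controls. Cluster 5 also held only 1 and 6 cells in mutant libraries 1 and 2, against 257 and 1419 in cluster 2. Doublets with mutant mesothelial cells whose markers were already lowered are not covered. That cluster 2 may hold cells of the mesothelial lineage altered by the loss of Myrf stays a hypothesis, found and tested on the same data.

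Mesothelial-like cells were nearly missing from mutants. A different mix of male and female embryos is argued against by the mean share of mesothelial-like cells, higher in controls by 51.7 points among cells with Xist alone and by 45.9 points among cells with Y-linked genes alone. For a loss of mesothelial-like cells with all other cells in unaltered proportions, the summed distance over the 9 remaining clusters cannot decide. The closest control and mutant libraries were only 0.699 points farther apart in composition than the farthest libraries of a genotype. Cluster 2 alone, picked after its skew was seen, made up 0.645% and 2.75% of the remaining cells in control libraries 1 and 2. It made up 63.0% and 33.3% in mutant libraries 1 and 2, which argues against unaltered proportions for that cluster. A lower yield of mutant mesothelial cells at dissociation or sorting may add to the difference in mesothelial-like cells and was not tested. The genotype, assigned first by shape, stays among the open explanations.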
